A study of Homo sapiens with 2 samples.

How the data were processed

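Polyadenylated RNA of BE(2)-C cells was measured after 7 days in EMEM/F12 or in HPLM, both with 10% serum and 1% penicillin-streptomycin, per the labels. RNA was extracted on silica columns and libraries were made with a TruSeq version 2 kit, which does not mark strand, per the labels' protocols. Trimmomatic 0.36, STAR 2.5.2b, Subread 1.5.2, DESeq2 without a version and build GRCh38 are named in the submitters' processing notes, with no role or order. The annotation release, the strand setting of the counting and any filter are not given in the sources used here.

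The authors deposited 1 table of the whole series, with 16051 lines that each hold a gene or a spike-in. Its log2 values are the authors' log2 fold changes of HPLM over EMEM/F12, per the file headers, with the direction taken from the library columns. Its p-values and adjusted p-values are the authors' own, per the file headers, and the deposited adjusted p equals a Benjamini-Hochberg adjustment over all lines with a p-value, with a largest difference of 1.25e-15. The 6 library columns hold a signal that the authors made by dividing read counts by a factor per library, as the deposited values show. Every deposited value was a whole multiple of a step near 1, so that whole reads could be recovered for 100% of values within a tolerance of 0.01 reads. DESeq2 1.42.0 run here on all recovered reads called the same 8908 lines as the authors' deposited table, out of 8908 in either, and 100% of the log10 p-values lay within 0.1. Of the lines, 46 are external RNA spike-ins and 16005 are genes, of which 16004 have a p-value, and 15955 matched GENCODE release 29 by identifier. That release was used only for coordinates on GRCh38, gene types, and the length and GC content of the longest annotated transcript of each gene. The lowest total over the 6 libraries was 61 reads, so genes below that level were not analysed here.

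The series lists 1 sample per medium, and the deposited table has 3 numbered columns per medium whose names match that sample. Under the rules fixed beforehand these count as repeat runs of 1 sample, so the design clause for a table of the authors' own comparison applied, with the authors' DESeq2 test as the main test at an adjusted p under 0.05. The edgeR test on recovered reads, which the design foresaw for usable replicates, was run as an added alternative. The set test camera was not run for the same reason, and each list's median is described by its percentile among random lists, with no p-value across genes. The libraries of a medium differed by more than sampling noise, with a chi-square per degree of freedom of 1.39 for EMEM/F12 libraries 1 and 2, 9.84 and 8.37 for library 3 against libraries 1 and 2, and 1.47 to 2.39 between HPLM libraries, so none was counted as a copy of another. In EMEM/F12 library 3, 333 genes lay at least 2-fold above the other libraries of its medium and 49 at least 2-fold below.

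From the deposited values, means and SDs over the 3 libraries of a medium and the log2 ratio of the means with its SE, propagated from the SDs, were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The log2 ratios of the named genes differed from the authors' log2 fold changes by at most 0.025. Figures were drawn with matplotlib 3.10.9. Read depth ranged from 17504237 to 21676080 reads per library. The limit that a count of 0 allows, 3 reads, corresponds to 2.68 to 3.49 normalised reads. That limit covers counting error only.

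Gene lists, marker lists and the rule for named genes were written before the data were examined. Named genes are the 10 called genes with the largest rise and the 10 with the largest fall among genes with a mean of at least 100. From each list they are up to 2 called members that rose most and up to 2 that fell most at that mean. MYCN, ASNS, SLC7A11, CD9, CD63, CD81, CAV1, SDC1 and LRP1 are named without regard to change. Some genes that these rules select are withheld for evaluation and are not reported here. Symbols follow the deposited table. The 51 lists hold 1002 of their 1054 entries in the table, and 5 marker lists cover fibroblast, Schwann and glial, endothelial, blood and epithelial cells. For each list the median log2 fold change over members with a mean of at least 10 was placed among the medians of 10000 random lists matched in 20 bins of mean expression. In addition, 7 lists were written later. The second fibroblast list and the histone list were written before their values were looked at. The lists of mitochondrial tRNAs, imprinted genes, Wnt antagonists, neuropeptides and potassium channels were written after some of their genes were seen.

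Alternatives fixed beforehand were adjusted p under 0.01 and 0.1, a recomputed adjustment, a minimum mean of 10 or 100, a log2 fold change of at least 1, recentring on the median gene, leaving out mitochondrial and ribosomal protein genes, DESeq2 on gene reads, no filter on low counts, the library number as a block, and each library left out in turn. For lists they were the mean in place of the median, a minimum mean of 100, all members, unmatched random lists and signed p-values. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr) in R 4.3.3, limma 3.58.1 on log2(value + 1), edgeR scaled by the spike-in reads, edgeR with loess trends in transcript length and GC content removed from each library, and the edgeR counts of each list without EMEM/F12 library 3. For list medians the settings with a library left out were also chosen then, and for named genes every setting but the recentring. Except for limma and DESeq2, each fit on reads used edgeR. With 200 of 16005 simulated genes changed, edgeR recovered 46% of changes of 1.25-fold, 78% of 1.5-fold, 90% of 2-fold and 100% of 4-fold, 50 genes each, and 13 unchanged genes were called, 7.65% of all calls and above the nominal 5%. In 100 simulated lists of 20 genes per setting, 3 lay above and 4 below the random range with no shift, and 51 and 98 lay above it with shifts of 0.5 and 1 on the log2 scale. The simulated genes varied independently.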

Results

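BE(2)-C is an established human neuroblastoma cell line with an amplified MYCN gene. Polyadenylated RNA was sequenced from cells kept for 7 days in a classical medium, EMEM/F12, or in HPLM, a medium made to hold metabolites and salts at levels close to those of human plasma. Both media carried 10% fetal bovine serum and 1% penicillin-streptomycin. The series lists 1 sample per medium, and the authors' deposited table holds 3 library columns per medium. The EMEM/F12 libraries held 19734416, 17504237 and 18904947 reads. The HPLM libraries held 20282930, 20991945 and 21676080 reads. Below, levels are normalised reads given as mean ± SD over the 3 libraries of a medium, and changes are log2 ratios of those means, HPLM over EMEM/F12, ± SE. A gene is said to rise or fall in HPLM where its adjusted p in the authors' deposited table was under 0.05. Nothing in the labels says whether the 3 libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

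The comparison asks how a plasma-like medium changes the transcriptome of neuroblastoma cells, in a series on metabolic programming and the uptake of extracellular vesicles. FUT1, which encodes a fucosyltransferase, rose from 88.3 ± 11.3 to 1319 ± 22.7 normalised reads (log2 ratio 3.90 ± 0.11). CHAC1, which encodes a glutathione-degrading enzyme, rose from 482 ± 76.6 to 3991 ± 112 normalised reads (log2 ratio 3.05 ± 0.13). PPP1R15A, which encodes a stress-induced partner of protein phosphatase 1, rose from 576 ± 119.9 to 5986 ± 64.6 normalised reads (log2 ratio 3.38 ± 0.17). CRH, the gene of corticotropin-releasing hormone, fell from 284 ± 23.3 to 8.31 ± 1.18 normalised reads (log2 ratio -5.09 ± 0.14). CCNE2, the gene of the S-phase cyclin E2, fell from 269.9 ± 15.9 to 24.9 ± 0.875 normalised reads (log2 ratio -3.44 ± 0.06). MYCN fell from 72489 ± 6913 to 29419 ± 887 normalised reads (log2 ratio -1.30 ± 0.08). On GRCh38 these genes are FUT1 (ENSG00000174951, chromosome 19, 48748011 to 48755390), CHAC1 (ENSG00000128965, chromosome 15, 40952962 to 40956519), PPP1R15A (ENSG00000087074, chromosome 19, 48872392 to 48876057), CRH (ENSG00000147571, chromosome 8, 66176382 to 66178725), CCNE2 (ENSG00000175305, chromosome 8, 94879770 to 94896678) and MYCN (ENSG00000134323, chromosome 2, 15940564 to 15947007). All are annotated as protein-coding, and reads were assigned to whole genes.

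Of 16004 genes with a p-value in the authors' deposited table, 4293 rose and 4612 fell, which is 55.6% of the genes. By at least 2-fold, 863 rose and 1077 fell, and by at least 4-fold, 185 rose and 160 fell. The other genes among the 10 largest rises were the mitochondrial tRNA genes MT-TK (3.89 ± 0.12), MT-TM (3.90 ± 0.23) and MT-TS1 (3.78 ± 0.46), KLHDC7B (3.59 ± 0.23), the long non-coding RNA AL365361.1 (3.56 ± 0.03), the neuronal membrane protein gene SLITRK6 (3.34 ± 0.15) and PRLHR, which encodes the prolactin-releasing hormone receptor (3.07 ± 0.02). The other genes among the 10 largest falls were KREMEN2, a Dickkopf receptor gene (-3.57 ± 0.17), ARHGAP36 (-3.48 ± 0.18), the apelin receptor gene APLNR (-3.42 ± 0.22), VSTM4 (-3.21 ± 0.16), IL17RD (-3.13 ± 0.10), CRB2 (-3.07 ± 0.17), TMEM119 (-3.01 ± 0.12) and FAM43B (-2.98 ± 0.12). Adjusted p-values in the authors' deposited table were 3.94e-240 for FUT1, 5.02e-84 for PPP1R15A, 2.16e-57 for CRH, 7.60e-56 for CCNE2 and 9.27e-123 for MYCN. The tRNA genes lie next to abundant mitochondrial transcripts and the library kit does not mark strand, so their reads are uncertain.

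The 51 gene lists fixed before the data were examined were set against 10000 random lists of the same size and mean expression. The median log2 fold change lay above the central 95% of the random medians for 14 lists and below it for 11. By chance 2.55 lists would fall outside if genes varied independently. Lists share genes, and members of a list can move together within a medium too, so the number outside is not a test. Of these 25 lists, 13 stayed outside on the same side under all of the 11 alternatives tried, and the 12 that did not are named with their groups below. The alternative with all members used the same genes as the main setting, because each had a mean of at least 10. It was therefore no separate check. Adjusted over the list alone, the counts of genes that rose and fell were unchanged for 46 of the 56 fixed and marker lists, and the other 10 are given with both counts. Where 5 or fewer members of a list moved in a direction, some are named beyond the rule for named genes, and these were chosen after their values were seen. In EMEM/F12 library 3 some list medians lay outside their random ranges relative to libraries 1 and 2. Several are given with their groups below. Others, on the log2 scale, were heat shock (0.10), hypoxia (0.07), p53 (0.06), ATF4 (0.05), unfolded protein response (0.05), NRF2 (0.04), mitosis (0.02) and zinc (0.49).

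**Figure D1:**
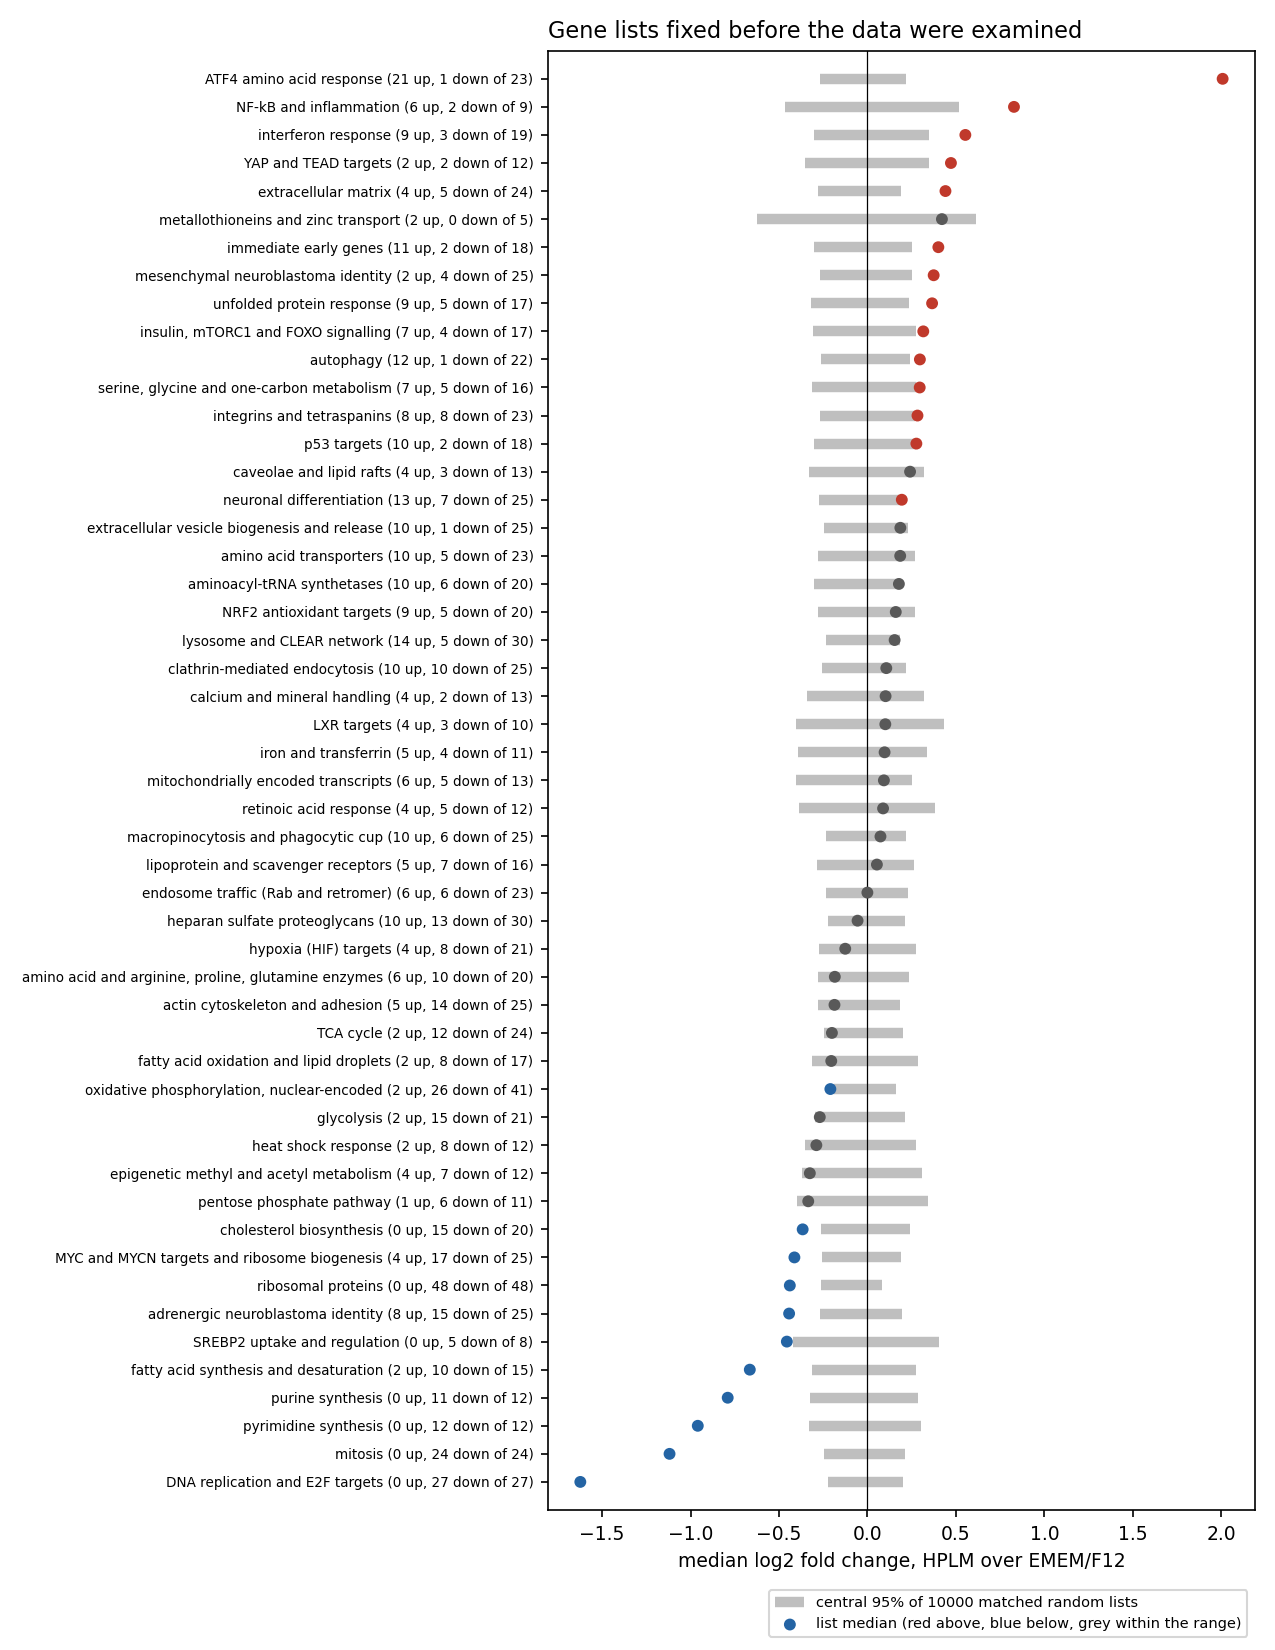
Median log2 fold change (HPLM over EMEM/F12, horizontal axis) of each of the 51 gene lists fixed before the data were examined, with the number of members that rose and fell beside each name. Points are list medians and grey bars the central 95% of 10000 matched random lists; the ATF4 list lies highest at 2.01 and the DNA replication list lowest at -1.62.

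Genes listed for the amino acid response of the transcription factor ATF4 rose together in HPLM. Whether ATF4 or the amino acids of the medium caused this was not tested. Of the 23 measured members, 21 rose, 1 fell and 1 did not pass. The member that fell was CBS, the gene of cystathionine beta-synthase (-0.18 ± 0.06), which has a near-identical copy in the build and is uncertain. SLC7A11, which encodes the cystine transporter (ENSG00000151012, chromosome 4, 138164097 to 138242349), rose from 311 ± 50.8 to 2403 ± 92.0 normalised reads (log2 ratio 2.95 ± 0.14). SLC7A11 stands in the amino acid transporter and NRF2 lists and not in the ATF4 list. ASNS, the asparagine synthetase gene, rose from 3749 ± 102 to 5775 ± 68.1 normalised reads (log2 ratio 0.62 ± 0.02). Among 23 amino acid transporter genes 10 rose and 5 fell (10 and 6 adjusted over the list alone), with SLC38A2 higher (1.92 ± 0.18) and the taurine transporter gene SLC6A6 lower (-1.13 ± 0.04). The cytosolic aminoacyl-tRNA synthetases split, with 10 of 20 higher, among them CARS (0.79 ± 0.03) and WARS (0.79 ± 0.02), and 6 lower, among them QARS (-0.84 ± 0.04). Of 20 enzymes of arginine, proline and glutamine metabolism 6 rose, with ASL, the argininosuccinate lyase gene, at 1.13 ± 0.05, and 10 fell, with the proline synthesis gene ALDH18A1 at -0.72 ± 0.03. In the serine, glycine and one-carbon list 7 of 16 rose, including PSPH (0.85 ± 0.06) and ALDH1L2 (0.74 ± 0.05), while 5 fell, including TYMS (-1.76 ± 0.07), MTHFD1 (-1.58 ± 0.03), SHMT1 and GCSH.

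Genes of the unfolded protein response of the endoplasmic reticulum followed in part, with 9 of 17 higher and 5 lower. HERPUD1 (2.03 ± 0.05) and DNAJB9 (1.77 ± 0.08) rose. MANF fell (-0.39 ± 0.06), as did CRELD2, PDIA4, PDIA6 and SDF2L1. Of the heat shock genes, more fell than rose, with 2 of 12 higher (BAG3 and HSF1) and 8 lower, including HSPA8 (-0.67 ± 0.02) and HSPE1 (-0.81 ± 0.06). NRF2 antioxidant genes were mixed, with 9 of 20 higher and 5 lower, and among the former HMOX1, which encodes heme oxygenase 1, rose from 199 ± 74.7 to 957 ± 14.5 normalised reads (log2 ratio 2.27 ± 0.31). Of 18 p53 targets 10 rose, led by GDF15 (2.68 ± 0.03) and BBC3 (1.29 ± 0.07), and BAX (-0.43 ± 0.05) and SESN1 fell. GDF15 is also a member of the ATF4 list, as are ATF3 among the immediate early genes and VLDLR among the lipoprotein receptors below. Of 22 autophagy genes 12 rose, with MAP1LC3B at 1.54 ± 0.02 and WIPI1 at 1.92 ± 0.18, and ULK2 fell (-0.45 ± 0.11). In the methyl and acetyl metabolism list 4 of 12 rose and 7 fell (4 and 8 adjusted over the list alone). MAT2A, which encodes the enzyme that makes S-adenosylmethionine, rose from 4733 ± 219 to 25915 ± 439 normalised reads (log2 ratio 2.45 ± 0.04), and the DNA demethylase gene TET1 fell (-1.45 ± 0.08).

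In the authors' deposited table the median log2 fold change was 2.01 for the ATF4 list (matched random lists -0.27 to 0.22), 0.37 for the unfolded protein response (matched random lists -0.32 to 0.23), 0.30 for autophagy (matched random lists -0.26 to 0.24), 0.28 for p53 targets (matched random lists -0.30 to 0.27) and 0.30 for serine, glycine and one-carbon metabolism (matched random lists -0.31 to 0.27), all above the random lists. Within the random range lay the medians in the authors' deposited table of 0.19 for amino acid transporters (matched random lists -0.28 to 0.27), 0.18 for tRNA synthetases (matched random lists -0.30 to 0.19), -0.18 for arginine, proline and glutamine enzymes (matched random lists -0.28 to 0.24), -0.29 for heat shock genes (matched random lists -0.35 to 0.28), 0.16 for NRF2 targets (matched random lists -0.28 to 0.27) and -0.33 for methyl and acetyl metabolism (matched random lists -0.37 to 0.31). The tRNA synthetase median lay above the range without EMEM/F12 library 3 (0.19), without HPLM library 3 and with signed p-values. The serine, glycine and one-carbon list differed in sign between its median and its mean, which was -0.14, and it lost its place outside the range under several alternatives, among them the fit without EMEM/F12 library 3 (0.25). The p53 list lost its place with members of mean at least 100, with unmatched random lists and without HPLM library 1 or 2.

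Genes of DNA replication, mitosis and pyrimidine synthesis fell without exception among the measured members of their lists. All 27 of 27 DNA replication and E2F target genes fell, as did all 24 of 24 mitosis genes, all 12 of 12 pyrimidine synthesis genes and 11 of 12 purine synthesis genes. CCNE1, the cyclin E1 gene, fell from 266 ± 14.9 to 57.4 ± 6.40 normalised reads (log2 ratio -2.21 ± 0.10). The mitotic kinase gene AURKB fell from 929.7 ± 4.13 to 287 ± 10.7 normalised reads (log2 ratio -1.70 ± 0.03). CCNA2, the cyclin A2 gene, fell as well (-1.45 ± 0.02). RRM2, which encodes a subunit of ribonucleotide reductase, fell from 3032 ± 16.9 to 674 ± 18.2 normalised reads (log2 ratio -2.17 ± 0.02). The guanine nucleotide synthesis genes IMPDH1 (-1.29 ± 0.06) and GMPS (-1.27 ± 0.03) fell too. All 48 of 48 ribosomal protein genes fell, with RPL3 (-0.93 ± 0.03) and RPL7 (-0.87 ± 0.01) lowest. Ribosomal protein genes have many processed copies in the genome, so single values are uncertain. In the list of MYC and MYCN targets and ribosome biogenesis 17 of 25 fell, including UTP20 (-1.23 ± 0.03), while MYC (0.68 ± 0.24), ODC1 (0.28 ± 0.02), RRP12 and PES1 rose.

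In the authors' deposited table the median log2 fold change was -1.62 for DNA replication (matched random lists -0.22 to 0.20), -1.12 for mitosis (matched random lists -0.24 to 0.21), -0.96 for pyrimidine synthesis (matched random lists -0.33 to 0.30), -0.79 for purine synthesis (matched random lists -0.33 to 0.29), -0.44 for ribosomal proteins (matched random lists -0.26 to 0.08) and -0.41 for MYC and MYCN targets and ribosome biogenesis (matched random lists -0.26 to 0.19). These 6 lists lay below the random lists under all alternatives tried. The lists overlap, since RRM2, TYMS and TK1 stand in both the replication and the pyrimidine list.

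Genes of cholesterol and fatty acid synthesis were mostly lower in HPLM. Of 20 cholesterol synthesis genes 15 fell and none rose, with ACAT2 at -1.20 ± 0.09. Of 8 genes of SREBP2 regulation 5 fell, including SREBF1 (-0.87 ± 0.06), STARD4, INSIG1 and SREBF2, and none rose. Of 15 fatty acid synthesis and desaturation genes 2 rose (ME1 and ACSL3, the latter not called with spike-in scaling, with length and GC trends removed, by limma or without EMEM/F12 library 2) and 10 fell (11 adjusted over the list alone), among them the desaturase genes FADS2 (-1.41 ± 0.05) and SCD5 (-1.37 ± 0.07). Of 10 LXR targets ABCA1 (1.13 ± 0.30), SMPDL3A, ABCG1 (0.67 ± 0.03) and NR1H2 rose, and APOE, LRP8 (-0.55 ± 0.07) and LPCAT3 fell. In fatty acid oxidation and lipid droplets PNPLA2 (0.28 ± 0.03) and ACADVL rose and 8 of 17 fell (9 adjusted over the list alone), led by HILPDA (-1.38 ± 0.05). In the authors' deposited table the lipid lists had medians of -0.37 for cholesterol synthesis (matched random lists -0.27 to 0.24), -0.46 for SREBP2 regulation (matched random lists -0.42 to 0.41), -0.67 for fatty acid synthesis (matched random lists -0.31 to 0.27), 0.10 for LXR targets (matched random lists -0.40 to 0.43) and -0.20 for fatty acid oxidation (matched random lists -0.31 to 0.29). The SREBP2 list came within the range when the random lists were not matched on expression.

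In glycolysis, the TCA cycle, nuclear oxidative phosphorylation and the pentose phosphate pathway more listed genes fell than rose. Mitochondrially encoded mRNAs and hypoxia targets moved in both directions. Of 21 glycolysis genes 15 fell, with ALDOC at -0.98 ± 0.09 and LDHB at -0.77 ± 0.01, while the glucose transporter gene SLC2A3 (1.14 ± 0.21) and the hexokinase gene HK2 (0.54 ± 0.03) rose. In the TCA cycle IDH1, which encodes the cytosolic isocitrate dehydrogenase, rose from 2979 ± 43.2 to 7704 ± 93.5 normalised reads (log2 ratio 1.37 ± 0.02). IDH2, which encodes a mitochondrial one, fell from 3422 ± 214 to 1137 ± 20.6 normalised reads (log2 ratio -1.59 ± 0.05). OGDH also rose, and 12 of 24 members fell. Of 41 nuclear genes of oxidative phosphorylation 26 fell (28 adjusted over the list alone), with SDHA at -0.74 ± 0.05, and COX6A1 (0.28 ± 0.03) and COX8A rose. Of the 13 mitochondrially encoded mRNAs 6 rose, led by MT-ND2 (0.75 ± 0.06), and MT-ND4L (-0.29 ± 0.05), MT-CO1, MT-CO2, MT-ND4 and MT-CYB fell. Of 11 pentose phosphate genes 1 rose and 6 fell, with PRPS2 at -1.35 ± 0.07. Among hypoxia targets VEGFA, the gene of vascular endothelial growth factor A, rose from 3472 ± 72.1 to 11694 ± 160.0 normalised reads (log2 ratio 1.75 ± 0.02), with P4HA2 (1.03 ± 0.05), BNIP3L and KDM3A, and 8 of 21 fell, with PFKFB3 at -0.55 ± 0.05.

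Medians in the authors' deposited table were -0.21 for nuclear oxidative phosphorylation genes (matched random lists -0.19 to 0.16), -0.27 for glycolysis (matched random lists -0.30 to 0.21), -0.20 for the TCA cycle (matched random lists -0.25 to 0.20), 0.09 for mitochondrially encoded mRNAs (matched random lists -0.40 to 0.25), -0.33 for the pentose phosphate pathway (matched random lists -0.40 to 0.34) and -0.13 for hypoxia targets (matched random lists -0.27 to 0.27). The oxidative phosphorylation list lay below the random lists, and it came within their range without EMEM/F12 library 3 (-0.21, where that range ended lower).

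The ferritin genes FTH1 (0.83 ± 0.05) and FTL (0.25 ± 0.03) rose with HAMP, IREB2 and NCOA4, and the transferrin receptor gene TFRC fell (-0.59 ± 0.02) with SLC40A1, SLC11A2 and STEAP3, among 11 iron genes. FTH1 and FTL have processed copies and are uncertain. Of 5 metallothionein and zinc transport genes SLC30A1 (0.56 ± 0.04) and SLC39A10 rose and none fell. By edgeR on recovered reads the number of these genes called was 2 with all libraries and 4 without EMEM/F12 library 3. Of 13 calcium and mineral genes ORAI2 (0.52 ± 0.06), RCAN1 (0.28 ± 0.05), CNNM2 and TRPM7 rose and STIM1 and ATP2A2 fell. For these 3 lists the medians in the authors' deposited table were 0.10 for iron (matched random lists -0.39 to 0.34), 0.42 for zinc (matched random lists -0.62 to 0.61) and 0.10 for calcium (matched random lists -0.34 to 0.32). Without EMEM/F12 library 3 the iron median was 0.21, still within the range, and in that library the list lay 0.0837 above libraries 1 and 2 on the log2 scale, outside its random range.

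Genes of routes by which vesicles can enter a cell moved in both directions. SDC1, which encodes the heparan sulfate proteoglycan syndecan 1 (ENSG00000115884, chromosome 2, 20200797 to 20225433), fell from 1788 ± 115 to 422 ± 16.2 normalised reads (log2 ratio -2.09 ± 0.06). CD9, which encodes a tetraspanin (ENSG00000010278, chromosome 12, 6199715 to 6238271), rose from 648 ± 31.0 to 2079.5 ± 55.0 normalised reads (log2 ratio 1.68 ± 0.05). CD63 rose from 5117 ± 86.4 to 6226 ± 18.3 normalised reads (log2 ratio 0.28 ± 0.01). CD81 fell from 5038 ± 173 to 4693 ± 101 normalised reads (log2 ratio -0.10 ± 0.03). CD81 had an adjusted p of 0.0408 in the authors' deposited table, and by edgeR with length and GC trends removed its log2 fold change was 0.0400, so its direction is not settled. LRP1 was at 4217 ± 1014 and 5643 ± 128 normalised reads and CAV1, the caveolin 1 gene, at 623 ± 408 and 979 ± 87.5. Their adjusted p in the authors' deposited table was 0.0639 and 0.284, so neither passed there. By edgeR the log2 fold change of CAV1 was 0.67 with all libraries and 1.34 without EMEM/F12 library 3, with adjusted p = 8.94e-21, and that of LRP1 0.45 and 0.63. LRP1 passed in both (adjusted p = 0.0114 and 1.09e-22) and CAV1 with all libraries did not (0.0896).

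Of 30 heparan sulfate proteoglycan genes 10 rose, including GLCE (1.48 ± 0.02) and AGRN (1.04 ± 0.09), and 13 fell, including SULF2 (-1.07 ± 0.10). Of 23 integrins and tetraspanins 8 rose and 8 fell (10 and 8 adjusted over the list alone), with TSPAN8 higher (1.26 ± 0.08) and the integrin genes ITGA9 (-1.78 ± 0.10) and ITGB5 (-1.60 ± 0.06) lower. Among 16 lipoprotein and scavenger receptors 5 rose, including VLDLR (1.33 ± 0.05), and 7 fell, including SCARB1 (-1.30 ± 0.06), or 7 and 7 adjusted over the list alone. Clathrin-mediated endocytosis had 10 of 25 higher, with EPS15 at 1.14 ± 0.07, and 10 lower, with the dynamin gene DNM1 at -0.76 ± 0.05. Macropinocytosis and the phagocytic cup had 10 of 25 higher, led by GULP1 (1.24 ± 0.12), and 6 lower, led by PAK1 (-0.87 ± 0.13). In caveolae and lipid rafts CAVIN2, ANXA2 (0.46 ± 0.09), FLOT1 and EHD1 rose and FLOT2 (-0.57 ± 0.08), EHD4 and PACSIN2 fell, of 13. By edgeR 7 caveolar genes were called with all libraries and 13 without EMEM/F12 library 3, where the list lay 0.54 above libraries 1 and 2 on the log2 scale.

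Of 25 vesicle biogenesis and release genes 10 rose, among them VPS37A (0.65 ± 0.05) and RAB27A (0.63 ± 0.08), and the sphingomyelinase gene SMPD3 fell (-0.36 ± 0.11). Of 30 lysosome genes 14 rose, with NEU1 at 0.88 ± 0.03 and the cathepsin gene CTSD at 0.65 ± 0.03, and 5 fell, including CTSF (-1.03 ± 0.09), GLA, CTSA and NAGLU. Endosome traffic had 6 of 23 higher, with RAB5A at 0.90 ± 0.06, and 6 lower, with SNX27 at -0.44 ± 0.07. Of 25 actin and adhesion genes ACTR2 (0.34 ± 0.05), TLN1, PXN, FLNA and ARPC2 rose and 14 fell, with CNN2 at -1.08 ± 0.13 and VCL at -0.89 ± 0.04. The median log2 fold changes of these uptake and traffic lists in the authors' deposited table were 0.28 for integrins and tetraspanins (matched random lists -0.27 to 0.27), -0.06 for proteoglycans (matched random lists -0.23 to 0.21), 0.05 for lipoprotein receptors (matched random lists -0.29 to 0.26), 0.11 for clathrin endocytosis (matched random lists -0.25 to 0.22) and 0.07 for macropinocytosis (matched random lists -0.23 to 0.22). For the others the medians in the authors' deposited table were 0.24 for caveolae (matched random lists -0.33 to 0.32), 0.19 for vesicle release (matched random lists -0.24 to 0.23), 0.15 for lysosomes (matched random lists -0.23 to 0.18), -0.00 for endosome traffic (matched random lists -0.24 to 0.23) and -0.19 for actin (matched random lists -0.28 to 0.18). Of these 10 lists the integrins and tetraspanins alone lay outside the random lists, and they came within the range under several alternatives, among them the mean of the members and the fits without EMEM/F12 library 1 or without HPLM library 1 or 2. Without EMEM/F12 library 3 the caveolar and lysosomal medians lay above the range, at 0.53 and 0.19. In that library the integrins and tetraspanins lay 0.12 above libraries 1 and 2 on the log2 scale, outside their random range (-0.11 to 0.03). Macropinocytosis (0.06), endosome traffic (0.04), actin (0.06) and clathrin endocytosis (0.01) lay above their ranges there as well.

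**Figure D2:**
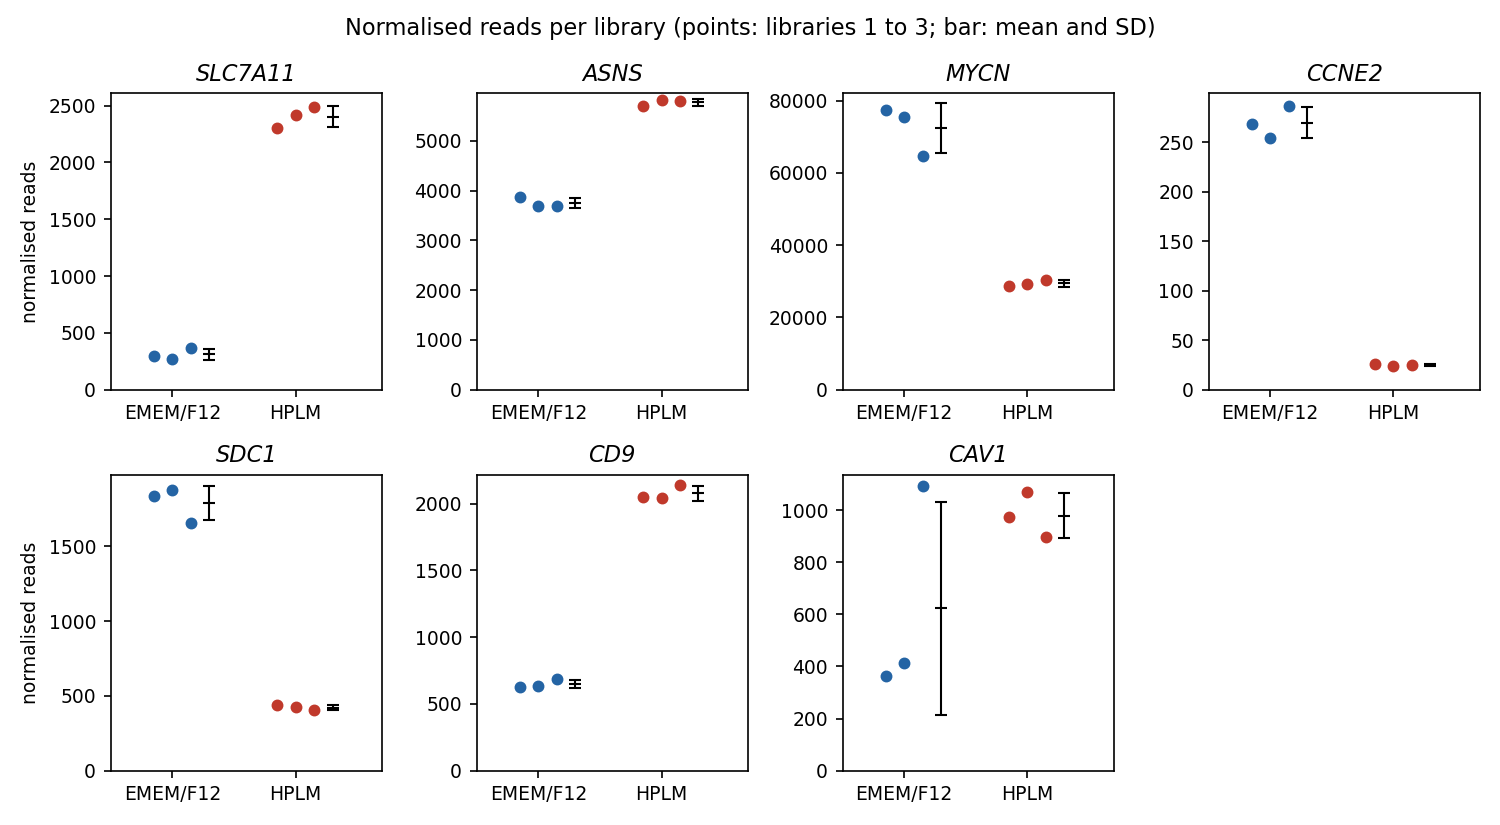
Normalised reads (vertical axis, from 0) of 7 genes in the 3 EMEM/F12 libraries (blue) and the 3 HPLM libraries (red), with the mean and SD beside the points. SLC7A11, ASNS and CD9 are higher and MYCN, CCNE2 and SDC1 lower in every HPLM library than in every EMEM/F12 library, while for CAV1 the point of EMEM/F12 library 3 lies above every HPLM library.

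Genes of adrenergic neuroblastoma identity were mostly lower in HPLM. The receptor kinase gene ALK fell from 675 ± 172 to 213 ± 33.8 normalised reads (log2 ratio -1.66 ± 0.25) and TFAP2B fell too (-1.34 ± 0.07). In all 8 of 25 adrenergic genes rose and 15 fell. Of 25 neuronal differentiation genes 13 rose, with PRPH, the peripherin gene, at 1.34 ± 0.03 and SCG2 at 1.05 ± 0.02, and 7 fell, with NPY at -1.53 ± 0.19 and STMN2 at -0.76 ± 0.03. In the retinoic acid list DHRS3, STRA6 (0.57 ± 0.06), RARA (0.40 ± 0.08) and RET rose, and 5 of 12 fell, including CRABP2 (-2.55 ± 0.07), RARG (-1.76 ± 0.07), ALDH1A3 and CRABP1. Medians of these lists in the authors' deposited table were -0.44 for the adrenergic list (matched random lists -0.27 to 0.20), 0.19 for neuronal differentiation (matched random lists -0.27 to 0.19) and 0.09 for the retinoic acid list (matched random lists -0.39 to 0.38). The retinoic acid median was 0.24 without EMEM/F12 library 3, and -0.69, below the range, over members with a mean of at least 100. The neuronal median came within the range under most alternatives, including without EMEM/F12 library 3 (0.13), and relative to libraries 1 and 2 the adrenergic median was -0.21 on the log2 scale in EMEM/F12 library 3.

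Mesenchymal, matrix and YAP target genes differed between the EMEM/F12 libraries, and a minority of them passed between the media. COL1A1 was at 21276, 22731 and 53749.7 normalised reads in EMEM/F12 libraries 1, 2 and 3 and 46001 ± 2748 in HPLM, and FN1, the fibronectin gene, at 9797, 12204 and 29563 and 24728 ± 2592. These genes were chosen after their values were seen, and neither passed. Of 25 mesenchymal genes FOSL2 (1.40 ± 0.04) and SNAI2 (0.59 ± 0.16) rose and PDGFRB (-1.48 ± 0.04), TWIST1, SMAD3 and HES1 fell. Of 24 matrix genes MMP2 (0.68 ± 0.03), TIMP1 (0.66 ± 0.20), LAMA5 and LAMB2 rose and TIMP2 (-0.64 ± 0.02), LAMB1, LAMC1, LAMA4 and TIMP3 fell (3 and 5 adjusted over the list alone). Of 12 YAP and TEAD targets NUAK2 and TEAD1 (0.49 ± 0.03) rose and ANKRD1 and ARHGEF17 fell (2 and 1 adjusted over the list alone). ANKRD1 was at 23.7, 45.3 and 5.19 normalised reads in EMEM/F12 libraries 1, 2 and 3 and 9.46 ± 3.32 in HPLM. By edgeR with all libraries it was not called (adjusted p = 0.0792). Of 7 fibroblast markers LUM fell (-0.98 ± 0.14) and none rose.

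By edgeR, 7 mesenchymal, 9 matrix, 3 YAP target and 1 fibroblast marker genes were called with all libraries, and 21, 23, 12 and 7 without EMEM/F12 library 3. In that library the median log2 ratio to EMEM/F12 libraries 1 and 2 was 1.00 for mesenchymal genes, 0.69 for matrix genes, 0.98 for YAP targets and 1.29 for fibroblast markers. Medians between the media in the authors' deposited table were 0.37 for mesenchymal genes (matched random lists -0.27 to 0.25), 0.44 for matrix genes (matched random lists -0.28 to 0.19), 0.47 for YAP targets (matched random lists -0.35 to 0.35) and 0.50 for fibroblast markers (matched random lists -0.50 to 0.48). Without EMEM/F12 library 3 these medians were larger, at 0.82, 0.72, 0.86 and 1.12. The medians of the mesenchymal genes, YAP targets and fibroblast markers came within the range without EMEM/F12 library 1 or without library 2 and under the mean of the members, among other alternatives, and that of the matrix genes when signed p-values replaced the fold changes. Among other markers, 1 gene was higher and S100B lower of 4 Schwann and glial genes, and CLDN4 (1.36 ± 0.11), KRT19 (1.15 ± 0.17), KRT8 and KRT18 were higher of 5 epithelial genes. Of endothelial and blood cell markers 1 and 1 were in the table and none passed. Their medians in the authors' deposited table were -0.33 for Schwann and glial genes (matched random lists -0.77 to 0.84), 0.95 for epithelial genes (matched random lists -0.66 to 0.75), 1.09 for the endothelial gene TEK (matched random lists -1.66 to 1.75) and -0.29 for the blood cell gene CD14 (matched random lists -1.83 to 1.92). Of these 4 the epithelial median alone lay outside the random lists, above them. Without EMEM/F12 library 3 the value of TEK, 2.09, lay above them as well and edgeR called it, and in library 3 it lay 2.07 above libraries 1 and 2. Without that library edgeR also called CD14, as lower, while its value, -0.38, stayed within the random range.

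**Figure D3:**
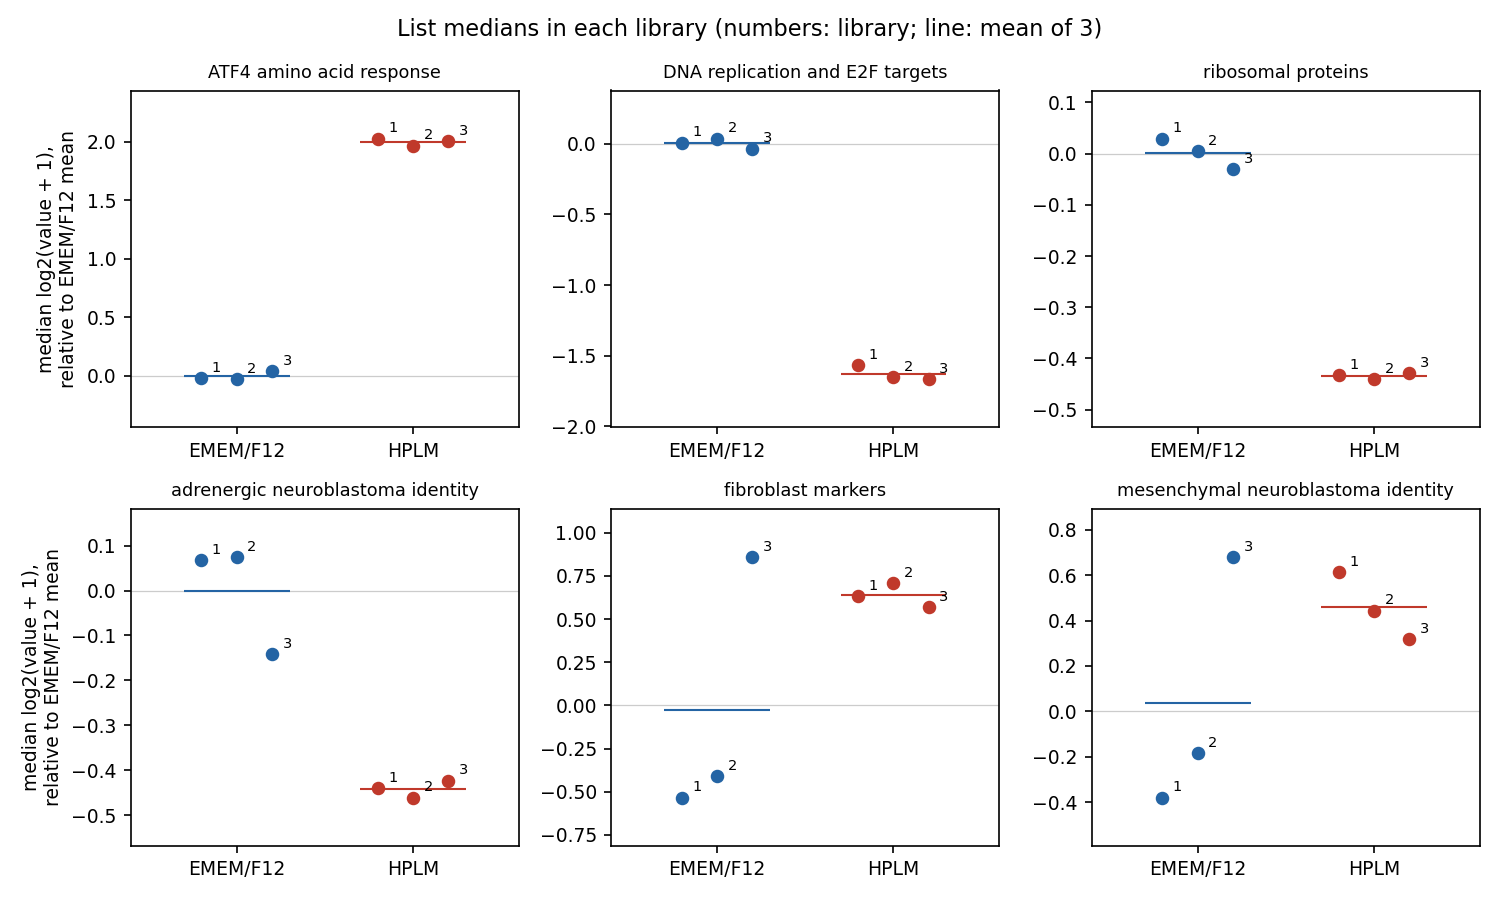
Median over the members of 6 gene lists of log2(value + 1) in each library, relative to the mean of the EMEM/F12 libraries (vertical axis); points are libraries, numbered, and lines the mean of the 3. The ATF4, replication and ribosomal protein lists separate the media, while in the fibroblast and mesenchymal lists EMEM/F12 library 3 lies with or above the HPLM libraries.

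Among signalling genes IRF1, which encodes an interferon-induced transcription factor, rose from 136 ± 13.1 to 579 ± 17.5 normalised reads (log2 ratio 2.09 ± 0.08). OAS3, which encodes an antiviral synthetase, fell from 1696 ± 124 to 425 ± 12.6 normalised reads. Of 19 interferon response genes 9 rose, including IRF7, and OAS1, OAS3 and IFI6 fell. Of 9 NF-kB and inflammation genes 6 rose (7 adjusted over the list alone), with RELB at 0.83 ± 0.21, and NFKB1 (-0.59 ± 0.03) and SOD2 fell. Of 18 immediate early genes 11 rose, with ATF3 at 2.01 ± 0.22 and ETV5 at 1.21 ± 0.04, and EGR1 (-1.12 ± 0.10) and NR4A1 (-1.04 ± 0.07) fell. In insulin, mTORC1 and FOXO signalling 7 of 17 rose, with IRS2 at 1.46 ± 0.07, and IGF2, INSR, PIK3IP1 and IGFBP3 fell. IGF2, the insulin-like growth factor 2 gene, fell from 119116 ± 8496 to 67696 ± 1260.2 normalised reads (log2 ratio -0.82 ± 0.06). Medians of the signalling lists in the authors' deposited table were 0.55 for interferon response (matched random lists -0.30 to 0.35), 0.83 for NF-kB (matched random lists -0.47 to 0.52), 0.40 for immediate early genes (matched random lists -0.30 to 0.25) and 0.32 for insulin signalling (matched random lists -0.31 to 0.27), all above the random lists. When signed p-values replaced the fold changes, the last 3 of these came within the range, and the NF-kB median did so under the mean of the members and over members with a mean of at least 100 as well. The insulin signalling median also did so against unmatched random lists. In EMEM/F12 library 3 the NF-kB list lay 0.42 above libraries 1 and 2 on the log2 scale, outside its random range.

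**Figure D4:**
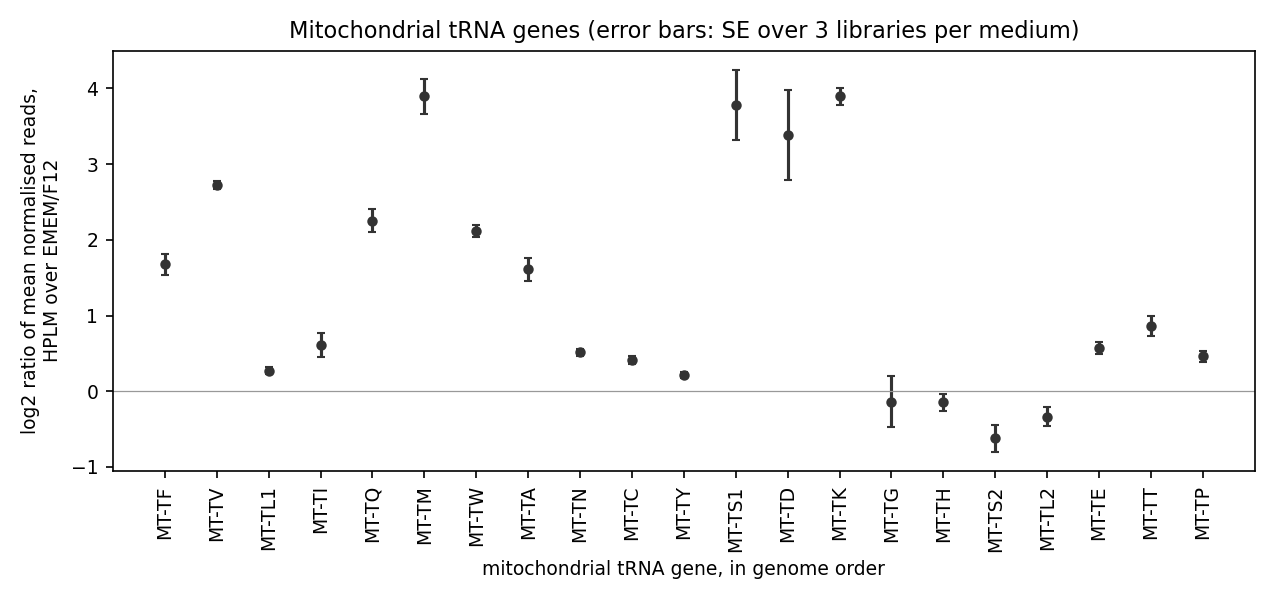
Log2 ratio of mean normalised reads, HPLM over EMEM/F12 (vertical axis), of 21 mitochondrial tRNA genes in the order of the mitochondrial genome, with error bars of 1 SE over 3 libraries per medium. MT-TK and MT-TM lie highest, at 3.89 and 3.90, and MT-TS2 lowest, at -0.62.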

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

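Chosen only after the result was seen were the tests of fibroblast-like cells in HPLM, of a wrong label, and of length, GC content and scaling for the ribosomal protein genes, the list values without EMEM/F12 library 3 and the alternatives with spike-in scaling or with length and GC trends removed. Spike-in RNA, which no label mentions, took 997099 of 119094555 reads, 0.837% of all reads, where a count of 0 would allow 2.52e-06%. Spike-in lines are left out of the gene counts here, but they are part of the authors' deposited table and of the adjustment of its p-values. The spike-in share was 0.808% ± 0.00419 in EMEM/F12 and 0.864% ± 0.0222 in HPLM (SD over the 3 libraries). In the authors' deposited table the median log2 fold change of the 46 spike-ins was 0.07, and 3 of them passed.

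The median of 7 fibroblast markers was lower in EMEM/F12 libraries 1 and 2 than in the other 4 libraries, and LUM went the other way. In EMEM/F12 library 3 it lay 1.29 above libraries 1 and 2 on the log2 scale (matched random lists -0.18 to 0.08). An HPLM library under a wrong label is argued against by the ATF4 list, which lay there at 2.65% of the distance to HPLM (95% bootstrap interval 0.698 to 14.8). A second fibroblast list, not looked at before, lay 0.14 above libraries 1 and 2 (random -0.11 to 0.01), so that RNA of fibroblast-like cells in a share that differs between libraries remains a candidate explanation for library 3. In HPLM the same list lay 0.00112 from libraries 1 and 2 (random -0.29 to 0.24), with 8 of its genes called lower. There the medium differs as well, so such RNA cannot be told apart from a response to HPLM. In library 3 only 12 of its 19 genes were above libraries 1 and 2, and the ratios were 0.941 for THY1, 1.10 for S100A6, 0.893 for PCOLCE, 0.951 for BGN and 0.98 for LUM against 2.44 for COL1A1 and 3.52 for COL3A1. Cells of the line itself in a mesenchymal state would raise part of the same genes and were not tested apart.

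All 48 ribosomal protein genes listed were lower in HPLM, with a median of -0.44 in the authors' deposited table. Scaled by the spike-in reads the median was -0.48 (95% bootstrap interval over genes -0.53 to -0.43), which argues against the scaling of the libraries. No label says whether the spike-ins were added per cell or per RNA amount, so a change in RNA per cell is not addressed by this. Random lists matched on transcript length had medians around -0.11 (-0.25 to 0.06) and on GC content around -0.0539 (-0.25 to 0.09). With both trends removed the median was -0.37 (-0.45 to -0.33), with 47 of 48 genes lower. That argues against either trend as the whole cause, as far as the longest annotated transcript of each gene describes it. Where a shorter transcript is the one expressed, a bias on its length or GC content is not addressed. The length value narrowly missed the bound that was written first, itself after the fall was seen, and the removal of the trends was taken as the criterion after that was seen. What stays open is a response to the medium, as a hypothesis that shares its direction with the fall of MYCN, and reads shared with processed copies of these genes were not tested.

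Over the 10 ways to split the 6 libraries into groups of 3, 1 gave as many genes as the media by edgeR, the real one, with 10258 genes, and the highest of the others gave 0. Each of the other splits mixes the media in both groups, so the difference between the media becomes spread within them. Counts of 0 follow from that, so the comparison cannot decide on chance. With 10 splits a share under 0.05 cannot be reached.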

How the results depend on the processing

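For the counts, edgeR in its default form, limma, spike-in scaling and removal of length and GC trends were chosen after seeing the data. So were the list medians with a library left out and, for named genes, all but the recentring. The main counts were 8905 genes changed, 4293 higher and 4612 lower. Only the demand for a log2 fold change of at least 1, by its construction, moved them by over 1.5 times, to 1940, 863 and 1077. The other alternatives gave 7497 (mean at least 100) to 10417 (edgeR with length and GC trends removed) genes, edgeR alone 10258, and 8849 genes were called by edgeR and by the authors, all in the same direction. With length and GC trends removed, 7 shared calls had the opposite direction. Leaving out each library in turn with edgeR gave 9382 to 11302 genes changed, 4605 to 5593 higher and 4560 to 5709 lower, with the most without EMEM/F12 library 3. Spike-in scaling gave 4481 higher and 5572 lower genes. The share of higher among called genes stayed within 10 points of 48.2% under each scaling.

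Lists outside the random range numbered 25 of 51 in the main setting, 19 to 25 under the alternatives and 22 to 25 with a library left out. The median of the serine, glycine and one-carbon list, 0.30, changed sign as the mean of its members (-0.14), where strong falls of TYMS and MTHFD1 weigh more. CD81 changed from -0.10 to 0.0400 with length and GC trends removed, and the cause was not tested. Of 223 named genes 213 kept direction and side of the 0.05 threshold when refitted, recentred or with a library left out (0.01 and 0.1 were not applied to them), and of 3122 values 27 lost the call, 12 gained it and 1 reversed. Calls were lost at least once by ACSL3, HSF1, CBS, ATP2A2, STIM1, ARHGEF17 and CD81 among others, and gained by LRP1 and CAV1. Of 56 list and marker medians 34 kept their place within, above or below the random range. Of 613 values 45 came within that range, 11 left it with their sign kept and 2 changed sign. The 2 were the serine, glycine and one-carbon list and the retinoic acid list, which left the range. Sign changes within the range were not counted, such as that of endosome traffic (-0.00 to 0.06 without EMEM/F12 library 3). The 11 were of tRNA synthetases, methyl and acetyl metabolism, amino acid transporters, glycolysis, NRF2 targets, caveolae, lysosomes and TEK.

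With the library number as a replicate block edgeR called 9865 genes. Same-numbered libraries deviated from the means of their media with correlations of -0.06, -0.03 and -0.10 across genes. These values show no shared deviation, but they cannot exclude that same-numbered libraries were handled together. With 200 of 16005 simulated genes changed, edgeR recovered 46% of the smallest simulated changes at the depth and spread of these libraries. In the data edgeR called 10258 genes, so that share does not carry over to them or to the authors' test. The effect of depth alone was not tested.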

Other observations

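The lists of mitochondrial tRNAs, imprinted genes, Wnt antagonists, neuropeptides and potassium channels, and the test against mitochondrial mRNAs, were chosen only after some of the values were seen, and 7 later lists were computed in all. Genes that restrain or report Wnt signalling were lower in HPLM, with 12 of 16 lower and none higher (12 adjusted over the list alone). DKK1, which encodes a secreted Wnt antagonist, fell from 957 ± 54.2 to 149 ± 13.2 normalised reads (log2 ratio -2.68 ± 0.09). Among imprinted genes 8 of 22 fell and GRB10, BLCAP and IGF2R rose, with the counts unchanged when adjusted over the list alone. DLK1, which encodes a Notch ligand relative, fell from 52550.5 ± 5077 to 13148 ± 297 normalised reads. RTL1 fell from 1975 ± 381 to 252 ± 69.6 normalised reads (log2 ratio -2.97 ± 0.28) and is uncertain because of its antisense transcript. Medians in the authors' deposited table were -0.76 for the Wnt list (matched random lists -0.31 to 0.36) and -0.08 for the imprinted genes (matched random lists -0.29 to 0.28). Without EMEM/F12 library 3 the imprinted median was -0.21, and in that library the list lay at -0.16 relative to libraries 1 and 2 on the log2 scale, outside its random range.

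Neuropeptide and potassium channel genes changed in both directions. Of 15 neuropeptide and receptor genes PRLHR, CALCA, ADCYAP1 (1.99 ± 0.07), VIP and GAL rose and 7 fell, among them CRH and APLNR. Of 19 potassium channel genes 6 rose and 8 fell, with KCNA3 rising from 194 ± 21.8 to 1549.6 ± 32.3 normalised reads. Of 14 histone genes 6 rose and 8 fell, with HIST1H2AC at 2.05 ± 0.09 and H2AFX at -1.73 ± 0.09, and histone genes share reads among copies and are uncertain. In the second fibroblast list FBN1 (0.75 ± 0.32), IGFBP7 and THY1 rose and 8 of 19 fell, with the elastin gene ELN at -1.55 ± 0.07. The counts of these 4 lists were unchanged when adjusted over the list alone. Medians in the authors' deposited table were -0.31 for neuropeptides (matched random lists -0.33 to 0.36), 0.08 for potassium channels (matched random lists -0.32 to 0.31), -0.19 for histones (matched random lists -0.35 to 0.29) and -0.13 for the second fibroblast list (matched random lists -0.27 to 0.24). Without EMEM/F12 library 3 the potassium channel median was 0.0112, and the neuropeptide median, -0.34, lay below its range. In that library the potassium channels lay at -0.19 and the histones at -0.17 relative to libraries 1 and 2, below their random ranges.

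Of 21 mitochondrial tRNA genes 16 had more reads in HPLM and MT-TS2 fewer (17 and 1 adjusted over the list alone), with MT-TK (mitochondrial genome, 8295 to 8364) at 33.5 ± 4.16 and 497 ± 31.2 normalised reads and a list median of 0.62 in the authors' deposited table (matched random lists -0.28 to 0.32). In EMEM/F12 library 3 the list lay 0.14 above libraries 1 and 2, outside its random range. A general rise of mitochondrial transcripts is argued against by the 13 mitochondrial mRNAs, whose median was 0.0929 (95% bootstrap interval -0.25 to 0.15). Reads shared with nuclear copies stay open, since the 11 copies looked at (median -0.13, -0.28 to 0.13) are of mRNA and rRNA genes and hold no tRNA sequence. For a shift in how well short transcripts were kept, 42 nuclear genes of under 200 nt had a median of -0.0837 (-0.50 to 0.17). Of these genes 25 have a mean under 20 and 26 are microRNA or snoRNA genes, a class often found within longer host transcripts, so such a shift cannot be told apart from a change in the cells. The tRNA genes, of 59 to 75 nt, ran from -0.62 to 3.90, a spread that length alone would not give unless reads of neighbouring transcripts enter. Among these neighbours MT-ND2, beside MT-TM, rose (0.75 ± 0.06), and MT-CO1, beside MT-TS1, and MT-CO2, between MT-TD and MT-TK, fell. Incompletely processed precursor transcripts were not tested.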
